A study of Mus musculus with 6 samples.

How the data were processed

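Pancreatic islets were isolated from mice that all carried RIP-Cre, a Cre recombinase driven by the rat insulin promoter, and Rosa26-rtTA, a doxycycline-activated transcription factor. The Jag1 group also carried tetO_Jag1, a doxycycline-responsive allele encoding the Notch ligand Jag1, and the control group did not. All mice drank doxycycline for 8 weeks, per the labels' protocols. RNA was made into stranded poly(A) libraries with a TruSeq kit, per the labels. There were 3 libraries in each group. The labels number the libraries but do not state that each came from a separate mouse, so p-values measure the spread between these libraries.

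The deposited gene table holds estimated counts per gene symbol, 1 column per library, with no normalization. The submitters' processing notes name bcl2fastq, kallisto and limma and the mouse build GRCm38 (mm10), without versions. How transcripts were summed to genes, and which annotation was used, is not given in the sources used here. The authors also deposited a table of their own limma comparison, which gives a log2 fold change and a mean log2 expression, a p-value and an adjusted p-value, and 2 further statistics treated here as a score each, per the file headers. Of the 34945 symbols in the count table, 34210 matched a gene name in GENCODE vM21, which is built on GRCm38; coordinates are from that annotation. A row that names no gene took 0.00896% to 0.0155% of each library's counts and was left out of library sizes and tests. No column belonged to any other sample.

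Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, which left 14073. Libraries were scaled by TMM, and the robust quasi-likelihood test compared Jag1 with control using all 6 libraries, without covariates. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are counts scaled by TMM library size, and log2 CPM used a prior count of 2. Means are given with the SD over 3 libraries, and log2 fold changes with their standard error (SE). Groups of 3 against 3 give 10 splits, so an exact 2-sided permutation test cannot go below p = 0.1.

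There were 28 gene lists, fixed before the data were examined, that covered Notch signalling, islet endocrine cell types, other pancreatic cell types, stress, cell cycle and metabolism. They were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 28 lists, and again with the correlation estimated from these libraries and with fry. Members were also adjusted over the list alone. Genes named in the text follow a rule fixed at the same time. It takes Jag1, the members with the smallest p in each list (up to 4), a set of 15 islet and Notch genes, and the 10 largest changes in each direction among called genes with separated groups. Where fewer than 5 genes pass in a direction, it takes the 5 with the smallest p instead, and this applied to both directions. Of the list members, only those of lists that passed the preset test are named one by one, and 3 genes that the rule takes are not reported here. Hs6st2, Gpc3, Ccdc160, Phf6, Ppy, Pyy and Mki67, and members named because they passed over their list alone, were chosen after their values were seen.

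The steps were tested on simulated data drawn from these libraries' means, sizes and dispersions over 14073 genes. For Jag1 versus control, 32.8% of genes changed 1.5-fold were recovered, 77.6% of those changed 2-fold and 95.5% of those changed 4-fold. Of 143 calls, 6 were false. With so many calls the adjustment is less strict than with the 3 calls made in the real data. Simulated dispersions followed their trend with abundance, so these shares can overstate recovery in the real data. With no gene changed, 0 genes and 1 list were called. Simulated genes varied independently of each other, so this count does not cover correlation between genes or differences in cell content between libraries. Library totals ranged from 14283469 to 34348729 counts. A count of 3, the limit that a count of 0 allows, corresponds to 0.0873 to 0.21 CPM. Shares of counts have exact Clopper-Pearson 95% intervals, and these and the limits cover counting error only.

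Alternatives covered other scalings, DESeq2 1.42.0, limma-voom, filters, the non-robust fit, a replicate block, exocrine acinar markers as a covariate or left out, and each library left out in turn. Leaving out Control 1 and Jag1 3 together was added after seeing the data. Transcripts sharing sequence with the 10 genes of smallest p were searched with BLAST 2.17.0 among GENCODE vM21 transcripts at a minimum of 85% identity over 100 bp. Figures were drawn with matplotlib 3.10.9.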

Results

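Transcript abundance was measured by RNA sequencing in islets of 3 control and 3 Jag1 mouse libraries. Library totals were 19770481, 17937723 and 14283469 estimated counts in Control 1 to 3, and 17817548, 34348729 and 17708341 in Jag1 1 to 3. Insulin transcripts (Ins1 and Ins2) took 11.4% to 18.8% of the counts. Transcripts of exocrine acinar cells, the enzyme-secreting cells that surround islets, took 15.2% (95% interval 15.2 to 15.24), 5.25% (5.244 to 5.264) and 0.617% (0.6128 to 0.6209) in Control 1 to 3. In Jag1 1 to 3 they took 1.24% (1.234 to 1.245), 4.05% (4.04 to 4.054) and 15.4% (15.42 to 15.46), so this share varied within both groups. The first principal component, with 35.7% of the variance, ordered the libraries mostly by it. On the second, with 21.1%, Control 1 to 3 lay at 20.9, 18.2 and 13.3 and Jag1 1 to 3 at -25.5, 3.2 and -30.1. The groups did not overlap on this axis, which chance gives in 10% of cases.

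The series asks what added Jag1 in beta cells does to islets, and the Jag1 transcript itself was compared first. Jag1 lies at chromosome 2, 137081456 to 137116644. It stood at 4.281, 4.015 and 4.012 CPM in the control libraries and at 837.6, 524.9 and 906.9 CPM in the Jag1 libraries. Its log2 fold change was 7.52 (SE 0.25), a 184-fold rise (adjusted p = 1.54e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The exact permutation test gave p = 0.1, the smallest that 10 splits allow. Every library followed its label. Counts per gene do not separate transcripts of the allele from those of the resident gene.

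**Figure D1:**
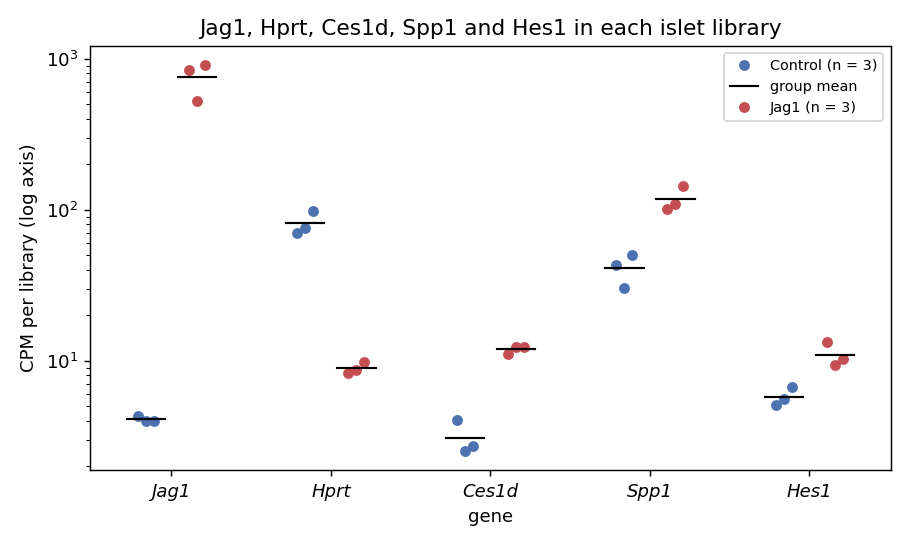
CPM of 5 genes (log axis) in each control and Jag1 library, with bars at the group means (n = 3 per group). Jag1 was at 4.012 to 4.281 CPM in the control libraries and 524.9 to 906.9 CPM in the Jag1 libraries, and Hprt was lower in every Jag1 library.

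Beyond Jag1, 2 genes changed. Hprt, which encodes the purine salvage enzyme hypoxanthine phosphoribosyltransferase, fell from 81.3 ± 14.7 to 8.95 ± 0.82 CPM (SD, n = 3 each), 9.09-fold lower (log2 fold change -3.18, SE 0.15, adjusted p = 1.38e-06 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Hprt lies at chromosome X, 52988137 to 53021659. Ces1d, a carboxylesterase gene at chromosome 8, 93166068 to 93197838, rose 3.84-fold from 3.10 ± 0.83 to 11.97 ± 0.75 CPM (log2 fold change 1.94, SE 0.22, edgeR adjusted p = 0.0071). Among genes that did not pass by edgeR, Spp1, which encodes osteopontin, had 41.3 ± 9.91 CPM in control and 118 ± 22.5 CPM in Jag1 libraries (edgeR adjusted p = 0.0813). Tm4sf1, a membrane protein gene, had 8.999 ± 0.16 and 17.7 ± 2.13 CPM (edgeR adjusted p = 0.0813). DESeq2 called both (adjusted p of 5.65e-13 and 0.000161).

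**Figure D2:**
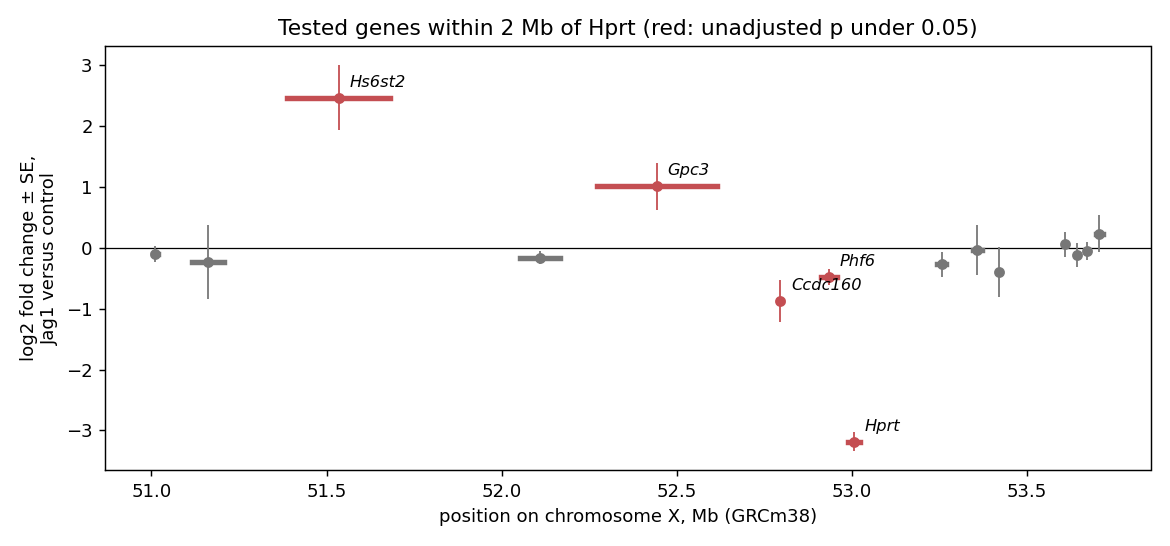
Log2 fold change (Jag1 versus control, 3 libraries each) with its SE for each tested gene within 2 Mb of Hprt, against its position in GRCm38; horizontal bars span the gene. Hprt stood at -3.18 and Hs6st2 at 2.47.

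The other genes of smallest p did not pass by edgeR either, while DESeq2 called Nap1l1, Gm21897, Gm21451, Gm48499 and Kansl2-ps (adjusted p from 0.00014 to 0.00673) and limma-voom called Gm48499 (adjusted p = 0.0235). With no filter on low counts edgeR called Kansl2-ps (adjusted p = 0.00901), Gm21897 (0.0121), Tm4sf1 (0.0131) and Gm48499 (0.0232). Nap1l1, a histone chaperone gene, had a log2 fold change of -0.71 (edgeR adjusted p = 0.204), and the predicted genes Gm21897 and Gm21451 had -1.02 (adjusted p = 0.0924) and -1.16 (adjusted p = 0.207). Gm48499 had 0 counts in the control libraries and 72 in the Jag1 libraries, at least 17.3-fold higher against a limit of 3 counts over the group. Kansl2-ps had 76 counts in the control libraries and 0 in the Jag1 libraries, at least 35.2-fold lower by the same limit (edgeR adjusted p = 0.0924 for both). Values of Gm48499, Gm21897, Gm21451, Nap1l1, Kansl2-ps, Spp1 and Ces1d are uncertain as far as the counting could split reads, since each shares sequence with other transcripts. The pseudogene Kansl2-ps matches Kansl2 over 1461 bp at 99.9% identity, and the longest match of Ces1d, with Ces1a, is 220 bp at 85.9%.

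Genes near Hprt were described after their values were seen: Hs6st2, a heparan sulfate sulfotransferase gene, had a log2 fold change of 2.47 (SE 0.54) and Gpc3, a glypican gene, 1.01 (SE 0.38), while Ccdc160 and Phf6 had -0.87 (SE 0.34) and -0.48 (SE 0.13), and none passed by edgeR (adjusted p of 0.464, 0.947, 0.955 and 0.82). DESeq2 called Hs6st2 (adjusted p = 0.0374).

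Of 14073 genes tested, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment thus called 3, of which 2 were higher and 1 lower. An unadjusted p under 0.05 was met by 700 genes, where 704 are expected by chance, and 1479 genes (10.5%) had groups that did not overlap, where chance gives 10%. DESeq2 called 36 genes, the 3 among them, and edgeR called 9 with no filter on low counts, 6 without Jag1 2, 5 without Jag1 3 and 7 without Control 1 and Jag1 3 together. The Ces1d call ended without Control 3 (edgeR adjusted p = 0.0521), without Jag1 1 (0.055) and with the replicate block (0.0695).

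Jag1 is a ligand of Notch receptors, and the series names islet Notch activity. Of 13 measured Notch target genes, 10 had positive values in Jag1 islets, with a median log2 fold change of 0.41. Camera with the preset correlation called the list upward (adjusted p = 3.59e-05), with adjusted p = 0.165 with an estimated correlation, where the estimate was 0.0697. Hes1, a transcriptional repressor induced by Notch, had 5.79 ± 0.80 CPM in control and 11.01 ± 2.06 CPM in Jag1 libraries (SD, n = 3; log2 fold change 0.93, SE 0.20). Sox9, a transcription factor of duct and progenitor cells, had 2.11 ± 0.67 and 4.55 ± 0.94 CPM (log2 fold change 1.09, SE 0.32). Both, named for their small p, lay higher in all 3 Jag1 libraries than in any control library. Of the 13 measured members, 5 had groups that did not overlap, against 10.5% of all genes tested. The repressor genes Hey1 and Heyl had log2 fold changes of 0.70 (SE 0.37) and 0.63 (SE 0.28), and Nrarp, a feedback inhibitor of Notch, had 0.63 (SE 0.30). Without Jag1 3, Hey1 had 0.40 and Heyl 0.33, and without Control 1 and Jag1 3 together Nrarp had 0.33.

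Lists of duct markers (median 0.29), stellate, pericyte and fibroblast markers (0.45) and immediate early and heat shock genes (0.47) were called upward as well, with tests given below. Fry did not call the Notch target list for a shift in 1 direction (adjusted p = 0.165) and called it for change in either direction (adjusted p = 0.0466). Over all genes tested, edgeR called no member and DESeq2 called Hes1 (adjusted p = 0.039). Adjusted over the list alone, 2 passed by edgeR (Hes1, adjusted p = 0.00723, and Sox9, adjusted p = 0.0326). Among the other Notch receptors and ligands, 7 of 9 measured members were higher, with a median log2 fold change of 0.16 (camera adjusted p = 0.0425, and adjusted p = 0.264 with an estimated correlation), and 0 passed over all genes by edgeR or DESeq2 or adjusted over the list alone by edgeR. Notch3, the receptor typical of pericytes and vascular muscle and also on the target list, had 0.45 (SE 0.18), and 0.24 without Jag1 3. The ligand genes Dll4, Dlk1 and Dll1 had 0.37, 0.37 and 0.21, with 0.23 for Dll4 without Jag1 2, 0.22 for Dlk1 without Jag1 1 and 0.14 for Dll1 without Control 1. The receptor genes Notch1 and Notch2 had -0.03 and 0.15, a sign that changed with the library left out for both. The receptor and ligand call ended without any 1 of Control 1, Control 2, Control 3, Jag1 2 or Jag1 3 (adjusted p of 0.0674, 0.0584, 0.149, 0.149 and 0.136), without Control 1 and Jag1 3 together (0.147) and with the replicate block (0.0518). The Notch signal transduction list did not pass (camera adjusted p = 0.848).

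**Figure D3:**
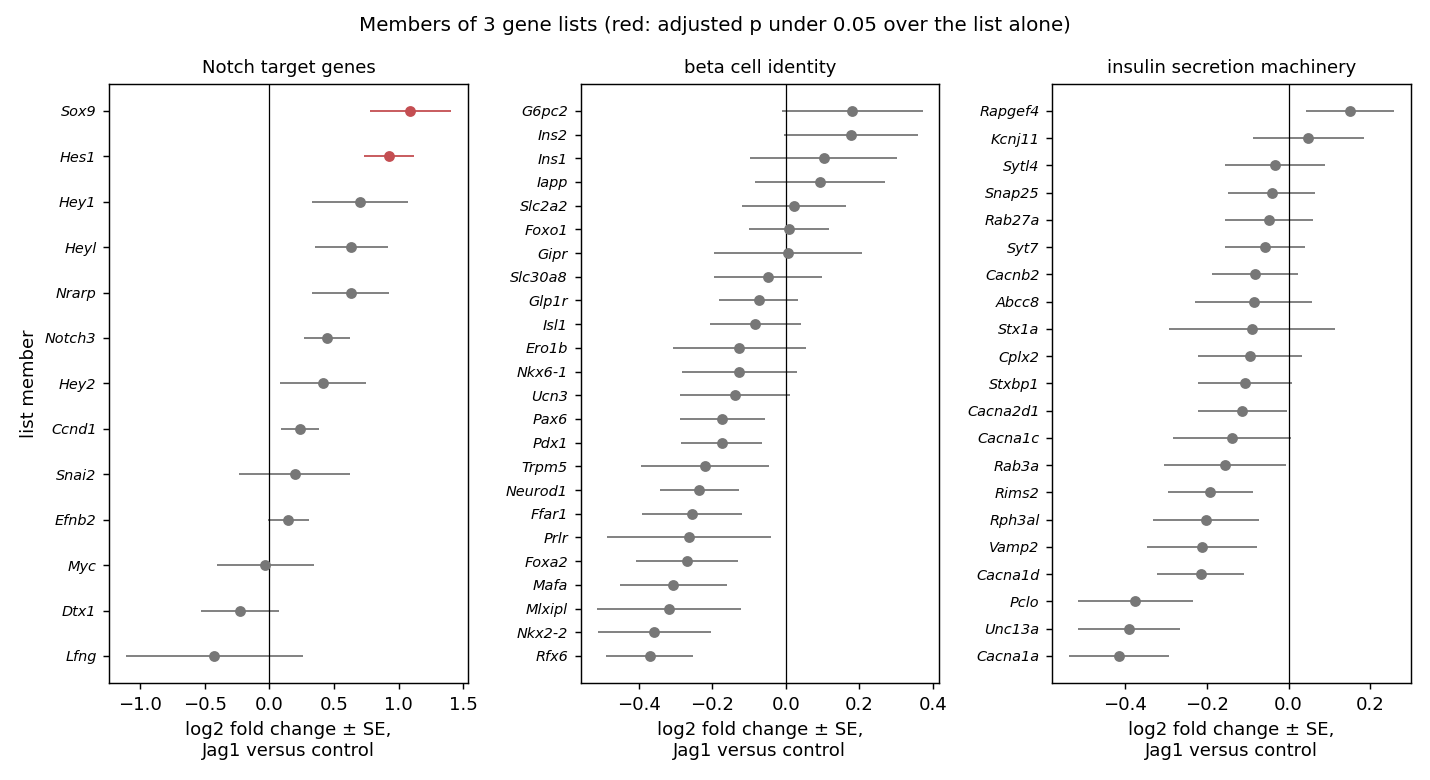
Log2 fold change (Jag1 versus control, 3 libraries each) with its SE for measured members of the Notch target, beta cell identity and insulin secretion machinery lists; members not reported here are not drawn. Hes1 and Sox9 (red) passed adjusted over the list alone, and no member of the other lists did.

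The series also names insulin secretory defects, and genes of the secretion machinery were slightly lower in Jag1 islets: 20 of 22 measured members had negative values, with a median log2 fold change of -0.11. Cacna1a, a voltage-gated calcium channel gene, had 53.0 ± 4.21 CPM in control and 39.8 ± 4.64 CPM in Jag1 libraries (SD, n = 3; log2 fold change -0.42, SE 0.12). Unc13a, a vesicle priming gene, had -0.39 (SE 0.12) and the presynaptic scaffold gene Pclo had -0.37 (SE 0.14), and -0.23 without Jag1 2. All 3, named for their small p, were lower in every Jag1 library than in any control library. Of the 22 measured members, 6 had groups that did not overlap, against 10.5% of all genes tested. Camera with the preset correlation called the list (adjusted p = 0.000295), with adjusted p = 0.165 with an estimated correlation. Fry did not call it for a shift in 1 direction (adjusted p = 0.112) and called it for change in either direction (adjusted p = 0.0369). No member passed over all genes tested by edgeR or DESeq2, or adjusted over the list alone by edgeR.

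Insulin itself did not differ beyond the spread between libraries. Ins1 and Ins2 had log2 fold changes of 0.10 (SE 0.20) and 0.18 (SE 0.18). Ins2 had 0.06 without Jag1 2, 0.32 without Jag1 3, 0.28 without Control 3 and 0.27 without Control 1 and Jag1 3 together. Among the beta cell identity genes, 18 of 25 were lower, with a median of -0.13. The transcription factor genes Rfx6, Nkx2-2, Neurod1 and Mafa had -0.37 (SE 0.12), -0.36 (SE 0.15), -0.23 (SE 0.11) and -0.31 (SE 0.15), and Pdx1 had -0.17 (SE 0.11). Mafa had -0.18 without Jag1 3. The glucose transporter gene Slc2a2 had 0.02 (SE 0.14). The sign changed with the library left out for Ins1 and Slc2a2. Camera called the list with the preset correlation (adjusted p = 0.00265), with adjusted p = 0.527 with an estimated correlation, and 0 members passed over all genes by edgeR or DESeq2 or adjusted over the list alone by edgeR. The call ended without Jag1 1 (camera adjusted p = 0.0536) and without Jag1 3 (0.136). It also ended without Control 1 and Jag1 3 together (0.079). Whole islets were sequenced, and alpha cell markers were lower too (median -0.46). Lower values on this list or the secretion machinery list thus cannot be placed in beta cells, and cell content was not tested for them.

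Markers of other islet cell types were compared in the same way. Alpha cell markers were lower, with 8 of 9 negative and a median of -0.46 (camera adjusted p = 4.09e-05, and adjusted p = 0.264 with an estimated correlation). Gcg, which encodes glucagon, had 45820 ± 10900 CPM in control and 25040 ± 9730 CPM in Jag1 libraries (log2 fold change -0.87, SE 0.32), with 1.42% of the counts in Jag1 2 and a log2 fold change of -0.58 without that library. Irx1, Irx2 and Ttr had -0.73, -0.70 and -0.58, and Irx2 had -0.46 without Jag1 2. Delta and gamma cell markers went both ways, with 5 of 8 lower, 3 higher and a median of -0.35 (camera adjusted p = 0.0425, and adjusted p = 0.598 with an estimated correlation), with -0.37 for the somatostatin gene Sst, -0.36 for Rbp4, -0.37 for Hhex and -0.81 for Crhr2. Sst had -0.23 without Control 2 and Crhr2 -0.51 without Jag1 3, and without Control 1 and Jag1 3 together Crhr2 had -0.26 and Hhex -0.20. The gamma cell hormone genes Ppy and Pyy, chosen after their values were seen, had 0.77 (SE 0.72) and 0.23 (SE 0.32), with 0.09 and -0.003 without Jag1 2 and 1.22 and 0.53 without Jag1 3. Pyy had 0.11 without Control 1, 0.39 without Control 2 and 0.12 without Jag1 1. No member of either list passed over all genes by edgeR or DESeq2, or adjusted over the list alone by edgeR.

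Duct markers were higher, with 12 of 14 positive and a median of 0.29 (camera adjusted p = 1.38e-07, and adjusted p = 0.113 with an estimated correlation). Over all genes edgeR called no member, while DESeq2 called Spp1 (adjusted p = 5.65e-13), as did edgeR with no filter on low counts (adjusted p = 0.0254), with the replicate block (0.00943) and without Control 2 (0.0453). By edgeR 2 members, Spp1 (adjusted p = 0.000404) and Car2 (adjusted p = 0.00878), passed adjusted over the list alone. Car2, a carbonic anhydrase gene, had a log2 fold change of 2.47 (SE 0.58) at 0.37 ± 0.14 CPM in control libraries. Anxa3 had 0.38. Stellate, pericyte and fibroblast markers had a median of 0.45 (camera adjusted p = 0.000642, and adjusted p = 0.527 with an estimated correlation). Of them, Rgs5 and Acta2, genes of pericytes and smooth muscle, passed adjusted over the list alone (edgeR adjusted p of 0.0136 and 0.0142). Over all genes edgeR called no member and DESeq2 called Rgs5 (adjusted p = 0.00853). Pdgfrb and Cspg4 had 0.39 and 0.45. Pdgfrb had 0.14 without Jag1 3, Cspg4 0.17 without Jag1 2 and Acta2 0.76 without Jag1 1. Endothelial markers had a median of 0.15 (camera adjusted p = 0.0174, and adjusted p = 0.667 with an estimated correlation), with 0.49 for Esam, 0.46 for Egfl7, 0.25 for Pecam1 and 0.20 for Esm1, and 0 members passed over all genes by edgeR or DESeq2 or adjusted over the list alone by edgeR. Without Jag1 2, Egfl7 had 0.18 and Esm1 0.10, without Jag1 1 Esm1 had 0.35, and without Jag1 3 Pecam1 had 0.09.

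Cell cycle genes were lower, with 19 of 22 negative and a median of -0.71 (camera adjusted p = 2.56e-11, and adjusted p = 0.247 with an estimated correlation). Cenpe, a kinetochore motor gene, had 3.38 ± 0.93 CPM in control and 1.22 ± 0.26 CPM in Jag1 libraries and was the 1 member past the threshold adjusted over the list alone (edgeR adjusted p = 0.0394). Over all genes edgeR called 0 members and DESeq2 called 2, Mki67 (adjusted p = 0.0132), chosen after its values were seen, and Top2a (adjusted p = 0.04). Mki67 had -1.35, Top2a -1.06, Ube2c -1.24 and Bub1 -1.23. Immediate early and heat shock genes, which are induced within minutes of stimulation or handling, were higher for 15 of 15 members, with a median of 0.47 (camera adjusted p = 1e-12, and adjusted p = 0.165 with an estimated correlation). Of these, 6 (Fos, Fosb, Jun, Junb, Ier2 and Dusp1) passed adjusted over the list alone and 0 over all genes by edgeR. DESeq2 called Fos, Fosb and Ier2 over all genes (adjusted p of 0.000138, 0.0381 and 0.0482), and edgeR called Fos without Jag1 2 (adjusted p = 0.000615). Fos had 50.01, 20.65 and 46.36 CPM in Jag1 1 to 3 and 14.2 ± 2.18 CPM in control libraries.

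Nuclear genes of oxidative phosphorylation had a median of 0.14 (camera adjusted p = 0.000428, and adjusted p = 0.264 with an estimated correlation), with 0.24 for Cox4i1, 0.24 for Uqcrfs1, 0.20 for Ndufv1 and 0.15 for Atp5a1. Mitochondrially encoded genes had a median of -0.34 (camera adjusted p = 0.00991, and adjusted p = 0.667 with an estimated correlation), with -0.50 for mt-Nd3, -0.48 for mt-Nd2, -0.55 for mt-Nd5 and -0.36 for mt-Nd4l. Without Jag1 3, mt-Nd3 had -0.33, and mt-Nd4l had -0.56 without Jag1 1 and -0.22 without Jag1 2. Without Control 1, mt-Nd2, mt-Nd5 and mt-Nd4l had -0.26, -0.16 and -0.16, and mt-Nd5 had -0.003 without Control 1 and Jag1 3 together. Genes normally low in beta cells had a median of 0.43 (camera adjusted p = 0.000186, and adjusted p = 0.527 with an estimated correlation), with 0.66 for Mgst1, 0.84 for Fcgrt, 0.83 for Ndrg2 and 0.83 for Cxcl12. Without Jag1 3, Ndrg2 had 0.26 and Cxcl12 0.12. The mean log2 CPM of the genes normally low in beta cells was 2.98 in Jag1 3. It was 2.11 and 1.88 in Jag1 1 and 2, and 1.67 to 2.34 in the control libraries. Whole islets were sequenced, so these values do not place the rise in beta cells. No member of these 3 lists passed over all genes by edgeR or DESeq2, or adjusted over the list alone by edgeR.

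The remaining 13 lists did not pass. Among them were prohormone processing (camera adjusted p = 0.374), dedifferentiation (0.586), lymphocytes (0.151), macrophages (0.687), Schwann cells (0.445) and adipocytes (0.875, 1 member measured). Of the dedifferentiation list, Sox9 was higher and passed adjusted over the list alone, while 6 of 9 measured members were lower (median -0.10). Endoplasmic reticulum stress (camera adjusted p = 0.58), inflammatory response (0.305) and glycolysis (0.188) did not pass either. Nor did 4 lists whose median and test differed in sign. These were acinar markers (median -0.07, camera upward, adjusted p = 0.95), interferon response (-0.02, upward, 0.785), cholesterol synthesis (-0.03, upward, 0.938) and hypoxia response (-0.06, upward, 0.555). Some of the 13 passed by camera in an alternative. Lymphocyte markers did without Control 3 (adjusted p = 0.000264) or Jag1 3 (0.0047). They also did with the acinar covariate (0.0372) and no filter (0.0449). Acinar markers passed upward without Control 1 (0.00593) or Jag1 1 (0.0136), and downward without Control 3 (0.00158) or Jag1 3 (0.000959). Schwann cell markers passed without Jag1 2 (0.0139), and macrophage markers, direction turned, without Jag1 3 (0.00697).

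In all, camera with the preset correlation called 14 of 28 lists, 8 upward and 6 downward, and with an estimated correlation it called 0. Lists whose estimate lay below the preset 0.01 lost their calls too: duct (0.00215), secretion machinery (-0.0242) and Notch receptors and ligands (-0.0629). For these, a correlation above the preset is not what ended the call. For the duct list the unadjusted camera p went from 1.48e-08 to 0.00402 although its estimate lay below the preset. The settings thus differ in more than the correlation. Calls lost with an estimated correlation therefore do not by themselves show that correlation between genes produced them. With an estimated correlation all 10 splits of the 6 libraries called 0 lists, so that setting told no grouping from another. Fry called 0 lists for a shift in 1 direction and 3 (Notch targets, secretion machinery, duct) for change in either direction. Without Jag1 3 the calls ended for genes normally low in beta cells (adjusted p = 0.62), endothelial (0.364), mitochondrial (0.364), delta and gamma cell (0.967) and stellate markers (0.942, direction turned). Without Control 1 they ended for endothelial (adjusted p = 0.158), mitochondrial (0.208) and delta and gamma cell lists (0.0563), without Jag1 2 for endothelial (0.487) and delta and gamma cell lists (0.0706), and without Control 2 for the latter (0.219). Without Control 1 and Jag1 3 together they ended for endothelial (adjusted p = 0.787), delta and gamma cell (0.876), mitochondrial (0.907) and stellate markers (0.746, direction turned). The stellate call also ended with limma-voom (adjusted p = 0.0511), the delta and gamma cell call with no filter on low counts (0.0685) and with the replicate block (0.0518), and the mitochondrial call with the replicate block (0.0501).

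**Figure D4:**
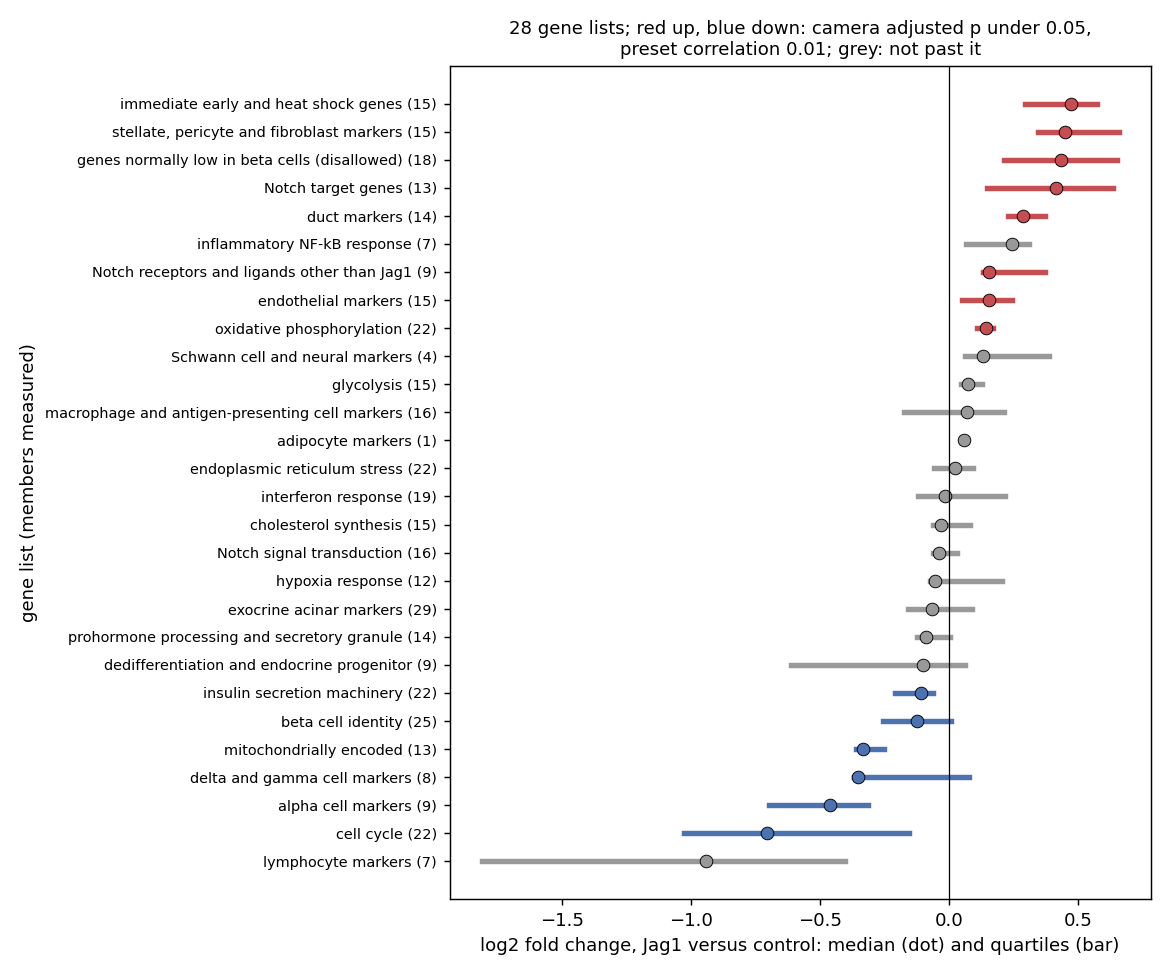
Median (dot) and quartiles (bar) of the log2 fold change (Jag1 versus control) over the measured members of each of 28 gene lists. Red and blue mark the 14 lists that camera called upward or downward with the preset correlation, and 0 of them were called with an estimated correlation.

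The authors' deposited table was set beside the edgeR fit; both rest on the same libraries, so they are not independent. The authors' deposited table lists 3 genes with an adjusted p under 0.05, Jag1, Hprt and Ces1d, the same 3 that edgeR called. In the authors' deposited table Jag1 has a log2 fold change of 7.47, Hprt -3.16 and Ces1d 1.97 (limma adjusted p of 3.49e-07, 3e-05 and 0.035). Across the 14073 genes in both, Pearson's r of the log2 fold changes was 0.916; genes are not independent replicates.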

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

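The alternatives without Control 1 and Jag1 3 together were chosen after seeing the data. Jag1 kept its direction and passed the threshold under every alternative run, with log2 fold changes from 7.37 without Jag1 3 to 7.73 without Jag1 2. Jag1 and Hprt were called under every setting that tests genes. The 3 calls became 36 with DESeq2 (25 higher and 11 lower), 9 with no filter on low counts (5 higher), 7 without Control 1 and Jag1 3 together (2 higher) and 8 at an adjusted p under 0.1, and ranged from 2 to 6 with 1 library left out. Among the 78 named genes other than Jag1, 1288 of 1324 comparisons with an alternative kept direction and side of the threshold. Of these genes only Hprt and Ces1d passed in the main fit, so most such comparisons were of genes that stayed short of it. In 24 comparisons a gene passed only in the alternative (15 of them with DESeq2), and 3 ended a call, all of Ces1d. Scaling moved the median of all genes from -0.0041 to 0.0138 at most. The Notch target list had camera adjusted p from 9.59e-06 to 0.00697 with 1 library left out, the secretion machinery list 0.000368 to 0.00596, and the beta cell identity list 8.31e-06 to 0.136. With an estimated correlation these were 0.165, 0.165 and 0.527, and with fry 0.165, 0.112 and 0.444. Without Control 1 and Jag1 3 together the beta cell identity list had adjusted p = 0.079. Of the 25 other lists, 11 were called, 8 to 12 with 1 library left out, 7 without Control 1 and Jag1 3 together, 0 with an estimated correlation and 0 with fry. Over all alternatives 358 of 448 comparisons of these lists kept direction and call, and 37 turned direction, whether or not the call changed. Of the comparisons that kept direction, 46 ended a call and 7 added one. Turned directions outside single libraries were acinar markers with DESeq2 size factors (adjusted p = 0.975), upper-quartile scaling (0.842), no filter (0.934), the replicate block (0.969), fry (0.992), and without Control 1 and Jag1 3 together (0.787). Others were macrophage markers with limma-voom (0.796) and the acinar covariate (0.941), adipocyte markers with no filter (0.758) and hypoxia with the stricter filter (0.944). Without Control 1 and Jag1 3 together, direction turned for dedifferentiation (0.489), stellate (0.746), macrophage (0.0201), lymphocyte (0.854), adipocyte (0.787), endoplasmic reticulum stress (0.0627), interferon (0.713) and cholesterol lists (0.787). With 1 library left out it turned somewhere for Ins1 (log2 fold change -0.085 to 0.21), Notch1 (-0.109 to 0.032), Notch2 (-0.029 to 0.353), Pyy (-0.003 to 0.527) and Slc2a2 (-0.037 to 0.093). It also turned for adipocyte (adjusted p from 0.624 to 0.962), cholesterol (0.289 to 0.87), dedifferentiation (0.15 to 0.942), endoplasmic reticulum stress (0.0605 to 0.942), acinar (0.000959 to 0.741), inflammatory (0.0676 to 0.87), interferon (0.312 to 0.978), lymphocyte (0.000264 to 0.697), macrophage (0.00697 to 0.529), Notch signal transduction (0.695 to 0.942) and stellate lists (7.81e-07 to 0.942). For all of these the cause was not tested. The replicate block called 3 genes, Jag1, Hprt and Spp1, with a Jag1 log2 fold change of 7.48, and the Ces1d call ended (edgeR adjusted p = 0.0695), as did the calls of 3 lists. The labels number the libraries but do not state that the numbers pair them. Deviations of same-numbered libraries correlated across genes at -0.19, 0.11 and -0.29. Control 1 and Control 3 matched another number best and Control 2 matched Jag1 2. These values do not settle whether libraries were paired. At this depth and n, 2-fold changes were recovered in 77.6% of simulated genes and 1.5-fold changes in 32.8%. The simulation made 143 calls, against 3 in the real data, so its adjustment was less strict and these shares can overstate recovery. Changes of the size seen in most lists were thus mostly beyond gene-by-gene detection.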

Other observations

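The tests of exocrine carry-over, lymphocyte, pericyte, duct and handling content and of the Hprt neighbourhood were chosen after the values they rest on were seen. The splits of the libraries and the search for Hprt-like genes were set before their results were seen.

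Hprt was 9.09-fold lower in the Jag1 libraries, and the genes near it on chromosome X were looked at next. Of 14 tested genes within 2 Mb of Hprt, 4 had an unadjusted p under 0.05 by edgeR, against 4.93% elsewhere. These were Hs6st2 (log2 fold change 2.47, SE 0.54), Gpc3 (1.01, SE 0.38), Ccdc160 (-0.87, SE 0.34) and Phf6 (-0.48, SE 0.13), chosen after their values were seen, and none passed adjustment over all genes by edgeR, while DESeq2 called Hs6st2 (adjusted p = 0.0374).

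Among GENCODE vM21 transcripts, reads moved to a similar gene do not account for the lower Hprt level. No other such transcript shared sequence with Hprt at the search limits, so the gain of similar genes was 0 CPM against 72.4 CPM lost. The annotation used for counting is not given, so a similar sequence outside vM21 is not excluded. Exocrine carry-over does not account for the lower Hprt level, since its log2 fold change was -3.17 (SE 0.15) with the acinar marker mean as a covariate. A candidate explanation that stays open is that the tetO allele, or DNA carried along with it from its strain of origin, lies at or near Hprt. It came from the neighbours' values, so their share with p under 0.05 (Fisher's exact test, 2-sided, p = 0.00402 within 2 Mb) describes what prompted it and is not evidence for it. Where the allele sits was not tested, and an effect of Jag1 on Hprt is not excluded.

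The cell cycle list was lower by 0.62 in mean log2 CPM. With the acinar marker mean as a covariate the difference was -0.62 (95% interval -1.23 to -0.02), and with the lymphocyte marker mean it was -0.59 (-1.16 to -0.01). Neither interval included 0, but the margin was narrow (nearest bounds -0.022 and -0.011). The tests were chosen after this list's values were seen, so they do not decide whether either source of cells was the whole cause. The list means were 2.90, 2.48 and 2.82 in Control 1 to 3, at 15.2%, 5.25% and 0.617% acinar counts, and 1.94, 2.03 and 2.36 in Jag1 1 to 3, at 1.24%, 4.05% and 15.4%, so they followed the acinar share in order within the Jag1 libraries but not within the control libraries. A part in the difference, or the whole of it, cannot be told apart with 6 libraries. An effect of the genotype on proliferation stays open and was not tested further.

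The Notch target list was higher by 0.38 in mean log2 CPM, while duct markers, pericyte genes and immediate early genes were higher too. With the stellate, pericyte and fibroblast marker mean as a covariate the difference was 0.32 (95% interval -0.11 to 0.76), with the immediate early and heat shock mean 0.33 (-0.75 to 1.41) and with the duct marker mean 0.25 (-0.83 to 1.32), with lower bounds of -0.114, -0.754 and -0.827. These intervals include both no difference and the whole of it, so a response to Jag1 cannot be told apart from cell content or handling of the samples with 6 libraries.

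The 10 splits of the 6 libraries are too few for a share under 0.05. For the count of genes, 1 split, the real one, reached 3 genes and the highest other gave 1. Splits that mix the genotypes also mix the Jag1 and Hprt levels within groups, so this count does not speak to chance for other genes. For the lists called with the preset correlation, 1 split, the real one, gave 14 and the highest other 13, and every other split called at least 6, so regroupings that mix the genotypes also produced many such calls. As -log10 of the camera p, the Notch target list had 5.29 (1 split as large, highest other 2.98), secretion machinery 4.13 (1 split, highest other 1.89), cell cycle 11.7 (1 split, highest other 9.69) and beta cell identity 3.02 (3 splits as large, highest other 5.9). Among the other called lists, 5 splits gave a value as large for genes normally low in beta cells and for stellate markers, 4 for endothelial and for delta and gamma cell markers, 3 for mitochondrially encoded genes and 2 for immediate early genes (13.4, highest other 17.4), the real one included. For the alpha cell, duct, oxidative phosphorylation and Notch receptor and ligand lists the real split alone did.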
